A study of Rattus norvegicus with 16 samples.

How the data were processed

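RNA from the left ventricle apex of male RccHan Wistar rats was measured on an Affymetrix whole-transcript array. The rats were 7 to 8 weeks old and ate a diet with 0 or 3000 ppm phenformin for 3 or 14 days. The protocol names 5 animals per group, and the 16 arrays analysed here fall into 4 groups of 4 by their labels, which call them biological replicates. Labelling started from 300 ng of total RNA, per the labels' protocols.

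The deposited values are intensities on a linear scale, 1 value for each of 68842 probe sets in each array. They were made with RMA, a background correction, quantile normalisation and probe set summary, per the submitters' processing notes, which give no version. How the summary was brought to this linear scale is not given in the sources used here, so every fold refers to the deposited scale. Array maxima lay between 999968 and 999974, above the range of a raw scan. The median residual SD was 0.0662 for genes of mean log2 above 18 against 0.14 for genes between 8 and 10, for a reason that was not tested; 160 genes exceeded a mean of 16. Array medians on the log2 scale lay between 4.94 and 5.13, and correlations between arrays between 0.984 and 0.991. The 99th percentiles of the arrays lay further apart, between 16.93 and 17.79 on the log2 scale. The highest was that of day 3 phenformin replicate 1. The number of arrays limits the precision of every value below.

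The log2 of each deposited intensity was taken without any further normalisation. The platform annotation gave exactly 1 gene symbol to 23446 probe sets and several symbols to 505, while 44891 were unnamed here. Of the probe sets with 1 symbol, the brightest over the 16 arrays stood for each gene, which left 22093 genes, 1182 of them with more than 1 probe set. The annotation gave a gene ID for 22246 of the probe sets with 1 symbol, and 22077 of these matched the current RefSeq genes; a single symbol, 1 in all, had changed. No filter on dim genes was applied.

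Genes were tested with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 16 arrays, moderated with a mean-variance trend, and a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were phenformin against control at day 3, the same at day 14, the difference between these effects, and day 14 against day 3 in controls. Files were read with version 1.17.8 of data.table. All p-values of genes are two-sided.

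Gene lists were drawn up from general knowledge of the heart, of biguanides and of the cell types a piece of ventricle can hold: 41 pathway lists and 15 lists of cell type markers. Camera, a test of a list against all other genes, was run on 55 of them with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The list of transcripts of mitochondrial DNA had under 5 measured members and was not tested. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, served as alternatives. The mean of each list in each array was compared with an exact two-sided permutation test of 4 against 4 arrays, whose 70 assignments allow no p under 0.0286.

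The genes named in the text were set by a rule. For each day these were the 6 genes past the threshold with the largest rise and the 6 with the largest fall whose 4 treated arrays lay apart from all 4 controls, leaving out provisional symbols and those of microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors. Where fewer passed, the genes of smallest p were added and are given as values. For each list past the list test, the rule added its 2 members with the largest change among those past the gene test, or else the 2 of smallest p. A fixed set of marker genes of mitochondrial, metabolic and cardiac stress was added whatever the result. The rule gave 55 genes at day 3 and 48 at day 14. Genes named outside the rule are said to be so. The list tests of the difference between days and of day 14 against day 3 in controls are not counted as fixed in advance. The lists, the rule, the other tests and the first set of alternatives were fixed before the data were examined.

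This first set dropped genes under the 25th or 50th percentile of mean level, normalised the arrays by quantiles again or aligned their medians, left out the mean-variance trend or made it robust, weighted the arrays, fitted only the 8 arrays compared, added the replicate number as a block, averaged the probe sets of a gene, tested all probe sets, required also a change of 1.5-fold or an adjusted p under 0.01, and left out each array in turn. For lists they were the other list tests above. Further alternatives were chosen after seeing the data: dropping genes of mean log2 above 16, normal scores of the ranks within an array in place of log2 values, and leaving out 2 arrays that stood apart in a principal component plot. The gene test was tested on simulated data of the same 22093 genes with the spread of these arrays. At day 3 it recovered 67.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, and at day 14 it recovered 56.7%, 80.6% and 98.5%. Of 185 and 165 genes called, 11 and 8 were false. Both days used the same gene means and spread, so the gap between them comes from the random draw and is no difference in power. Noise was drawn separately for each gene, so shifts shared by many genes of an array were not simulated. The real comparisons called fewer genes than the simulated ones, 125 at day 3 and 16 at day 14. Adjustment sets a stricter limit on p where fewer genes pass. Recovery in the real data can therefore be lower than these shares, above all at day 14. Probe sets with several symbols and unnamed probe sets stayed out of the gene test, since no single gene could be given to them.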

Results

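Gene expression in the left ventricle apex was measured on 16 arrays: 4 from control rats and 4 from phenformin-fed rats killed on day 3, and the same numbers on day 14. Phenformin is a biguanide, a drug class that lowers blood glucose and inhibits complex I of the mitochondrial respiratory chain. It was given in the diet at 3000 ppm. Expression is given as the log2 of the deposited array intensity, changes are phenformin minus control with the standard error (SE) of the limma fit, and n = 4 arrays per group throughout.

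The day 3 comparison asks how the heart changed after 3 days on the drug. Nr1d1 and Nr1d2, which encode the clock repressors REV-ERB alpha and REV-ERB beta, rose 8.58-fold (log2 change 3.10, SE 0.342) and 4.29-fold (2.10, SE 0.229), each with adjusted p = 0.00105. Mki67, a marker of dividing cells, fell by 2.75 on the log2 scale (SE 0.389, adjusted p = 0.00674), and Top2a, a DNA topoisomerase of dividing cells, fell by 1.89 on the log2 scale (SE 0.27, adjusted p = 0.0068). Txnip, a thioredoxin-binding protein that restrains glucose uptake, rose 3.95-fold, and the related arrestin Arrdc4 rose 2.02-fold (adjusted p = 0.014 and 0.016). The nuclear receptor Nr4a1, an immediate early gene, fell by 2.48 on the log2 scale (SE 0.428, adjusted p = 0.014).

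Lpar6, a receptor for lysophosphatidic acid, rose 2.34-fold at day 3 (log2 change 1.23, SE 0.212). The glutathione S-transferase gene Gstm4 rose by 1.19 on the log2 scale (SE 0.213). Among the genes that fell were the deubiquitinase Otud1 (log2 change -2.585, SE 0.527, adjusted p = 0.0343), the histone gene Hist2h3c2 (-1.97, SE 0.354) and the clock gene Per1 (-1.86, SE 0.359, adjusted p = 0.0251). Errfi1, a feedback inhibitor of EGF receptors, changed by -1.80 (SE 0.344), the stress transcription factor Atf3 by -1.69 (SE 0.342, adjusted p = 0.0322) and the phosphatase subunit Ppp1r15a by -0.93 (SE 0.154). Nr1d1, Nr1d2, Mki67 and Top2a stayed past the threshold without any single array. The other 11 of these 15 genes each missed it without between 1 and 7 of the arrays, always day 3 control replicate 1, 2 or 3 or a day 3 phenformin array, with adjusted p of up to 0.122.

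**Figure D1:**
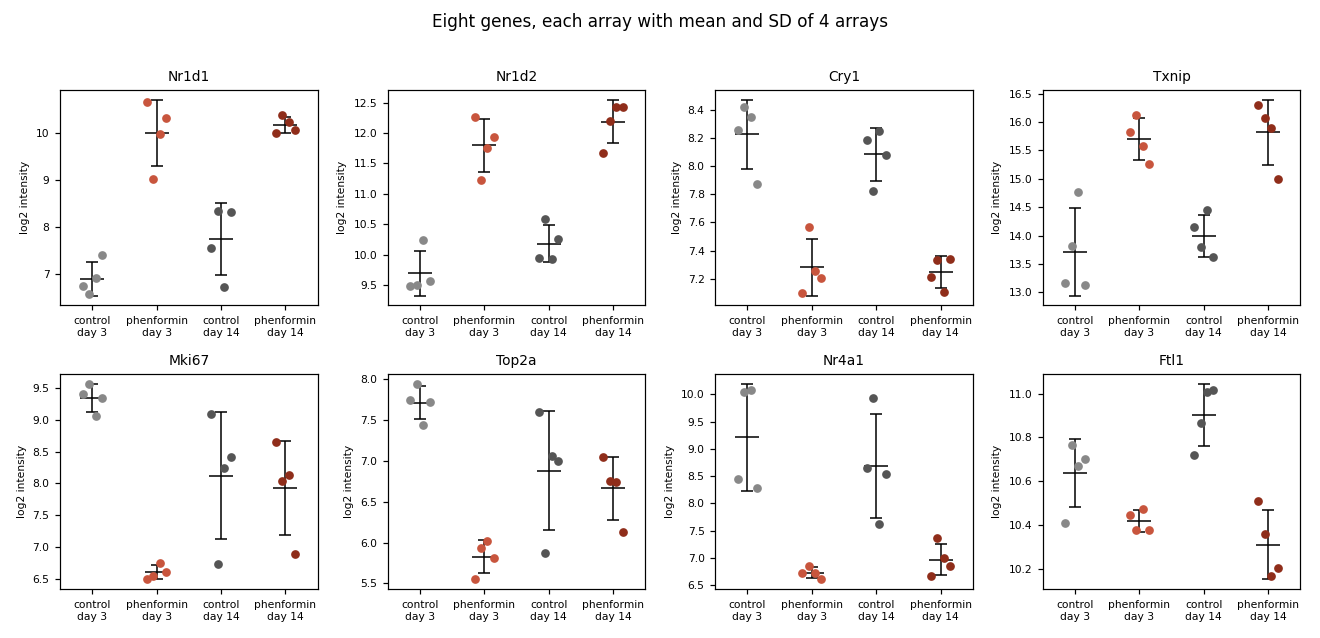
Log2 intensity of 8 genes in each of the 16 arrays, by group on the horizontal axis; points are arrays, and black bars give the mean and SD of 4 arrays. Nr1d1 and Nr1d2 lay above the controls in every treated array at both days, whereas Mki67 in day 3 controls had a mean of 9.34 against 6.60 in treated arrays, and of 8.12 against 7.93 at day 14.

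In all, 125 of the 22093 genes passed the threshold at day 3, 23 of them higher and 102 lower with phenformin, and 83 also differed at least 1.5-fold. In each of the 125 genes the 4 treated arrays lay apart from the 4 controls. In all 2072 genes had an unadjusted p under 0.05, where 1105 were expected by chance. The count depended on single arrays: it was 49 without day 3 control replicate 1, 22 without replicate 2 and 66 without replicate 3, and 55, 75, 62 and 33 without day 3 phenformin replicates 1, 2, 3 and 4. It was 74 with the array medians aligned, 16 over all probe sets and 23 without 2 arrays that stood apart, an alternative chosen after seeing the data.

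Genes of the cell cycle were lower as a group at day 3. Of the 35 measured members of that list, 15 fell past the threshold over all genes and 30 were lower adjusted over the list alone, with a mean log2 change of -0.725 (list test adjusted p = 5.59e-40). The adjusted p = 0.189 with an estimated correlation and 0.0113 by fry. Immediate early genes, which respond within minutes to stimuli, were below 0 in 25 of 25 members with a mean of -0.819. Of these, 2 fell past the threshold, Nr4a1 and Atf3, and 19 were lower adjusted over the list alone. That list had adjusted p = 4.04e-16 with the preset and adjusted p = 0.305 with an estimated correlation. Its mean per array was 0.48 ± 0.507 (SD) in day 3 controls and -0.339 ± 0.0826 in treated arrays, so the controls were both high and widely scattered. With this list mean as a covariate, chosen after seeing the data, 2 genes were called at day 3. The list lay lower in all treated arrays, so for the genes lost this cannot tell the drug from a change at dissection.

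The circadian clock list held genes that moved apart: of 21 members, 2 rose past the threshold (Nr1d1 and Nr1d2) and 4 fell, and 2 were higher and 10 lower adjusted over the list alone. Its mean was -0.0668 (list test adjusted p = 0.00646, and adjusted p = 0.407 with an estimated correlation). Of 20 glucocorticoid targets, 3 fell past the threshold, Per1 and Errfi1 among them, with a list mean of -0.352. In it 1 was higher and 7 lower adjusted over the list alone, and the adjusted p = 0.407 with an estimated correlation. The integrated stress response list of 41 ATF4 targets had 1 member past the threshold higher and 2 lower, Atf3 and Ppp1r15a, and a mean of -0.157 (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.386 with an estimated correlation). Its textbook markers did not pass the test at day 3: Gdf15 had a log2 change of -0.15 (SE 0.126), Fgf21 of -0.083 (SE 0.151), Trib3 of -0.059 (SE 0.168), Asns of -0.25 (SE 0.0772) and Mthfd2 of -0.35 (SE 0.123).

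Lists of fuel metabolism shifted by little. PPAR alpha targets had 1 of 27 members past the threshold (Txnip) and 4 higher adjusted over the list alone, with a mean of 0.286 and adjusted p = 0.386 with an estimated correlation. Fatty acid oxidation had a mean of 0.148 over 29 genes, 0 past the threshold in limma and 1 higher adjusted over the list alone (adjusted p = 0.386 with an estimated correlation). Its members of smallest p were Eci1 (log2 change 0.48, SE 0.114, adjusted p = 0.0755) and Hadhb (0.24, SE 0.0754). The citric acid cycle list had a mean of -0.087 (Pc -0.43, Idh3a -0.25; adjusted p = 0.63 with an estimated correlation). The fatty acid synthesis list had a mean of -0.176 (Elovl6 -0.74, Elovl5 -0.28; adjusted p = 0.386 with an estimated correlation). The members lower adjusted over the list alone were 1 and 0.

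Among structural and stress genes at day 3, the adult sarcomere list had a mean of 0.108 over 19 genes and 2 members higher adjusted over the list alone, with adjusted p = 0.63 with an estimated correlation. Tcap (log2 change 0.99, SE 0.233, adjusted p = 0.0733), Myom2 (0.59, SE 0.149), the beta myosin heavy chain gene Myh7 (0.77, SE 0.192, adjusted p = 0.0958) and the atrial natriuretic peptide gene Nppa (1.36, SE 0.42, adjusted p = 0.214) did not pass the test. Myom2 and Myh7 have mean log2 values of 18.46 and 19.12, near the array maximum. The list kept its call in 17 alternatives and lost it in 11. These were both other list tests, quantiles normalised again, medians aligned, array weights, and the leaving out of day 3 control replicate 1, 3 or 4 or day 3 phenformin replicate 1. The call was also lost without genes above a mean of 16 and without both arrays that stood apart, alternatives chosen after seeing the data. Other marker genes had log2 changes at day 3 of 0.13 (Nppb, SE 0.365), 0.26 (Pdk4, SE 0.771), 0.38 (Cpt1a, SE 0.169), 0.63 (Angptl4, SE 0.358), 0.49 (Ucp3, SE 0.314), -0.15 (Ppargc1a, SE 0.15), 0.078 (Nqo1, SE 0.0776), -0.36 (Hmox1, SE 0.184), 0.24 (Dbp, SE 0.206), -0.49 (Bmal1, SE 0.15) and -0.30 (Fkbp5, SE 0.121). None of these passed the test. Cytosolic heat shock genes had a mean of -0.214, with Dnajb1 at -0.64 (SE 0.148, adjusted p = 0.0692) and Chordc1 at -0.56 (SE 0.166), 5 of 16 lower adjusted over the list alone and adjusted p = 0.493 with an estimated correlation. Cytosolic ribosomal proteins were above 0 in 48 of 49 members with a mean of 0.181 (Rpl10 0.28, Rps4x 0.30) and 0 past the test either way (adjusted p = 0.407 with an estimated correlation). Interferon-stimulated genes were above 0 in 27 of 28 members with a mean of 0.237 (Mx2 1.04, SE 0.494; Irf9 0.24), and their adjusted p = 0.706 with an estimated correlation.

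Matrix genes and markers of some other cell types were lower as lists at day 3, by the list test with the preset correlation only. These calls were lost with an estimated correlation and by fry, and no gene named in this paragraph passed the test over all genes. The collagen and matrix list had a mean of -0.371 over 38 genes, with Fn1 at -0.98 (SE 0.235, adjusted p = 0.0808), Col3a1 at -0.91 (SE 0.225) and Col1a1 at -0.84 (SE 0.231), and 9 members lower adjusted over the list alone. Its adjusted p = 0.407 with an estimated correlation. Fibroblast markers had a mean of -0.381 over 18 genes (Mfap4 -1.04, SE 0.238; 6 lower adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). Macrophage markers had a mean of -0.232 over 18 genes (Mrc1 -0.57, Cd68 -0.36; 3 lower adjusted over the list alone; adjusted p = 0.386 with an estimated correlation). Red blood cell markers were below 0 in 10 of 10 genes with a mean of -0.433 (Slc4a1 -1.01, SE 0.226; Epb42 -0.47; 2 lower adjusted over the list alone; adjusted p = 0.386 with an estimated correlation). The endothelial list mean was 0.0932 ± 0.0615 (SD, n = 4) in controls and 0.146 ± 0.069 in treated arrays, relative to the 16-array mean, with exact permutation p = 0.314. In all 17 of the 55 lists passed the list test at day 3, 5 higher and 12 lower. With camera 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and 1 passed fry. Regrouping the same 8 arrays gave a median of 9.5 lists over the other 34 splits, so a call of this list test alone carried little weight.

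**Figure D2:**
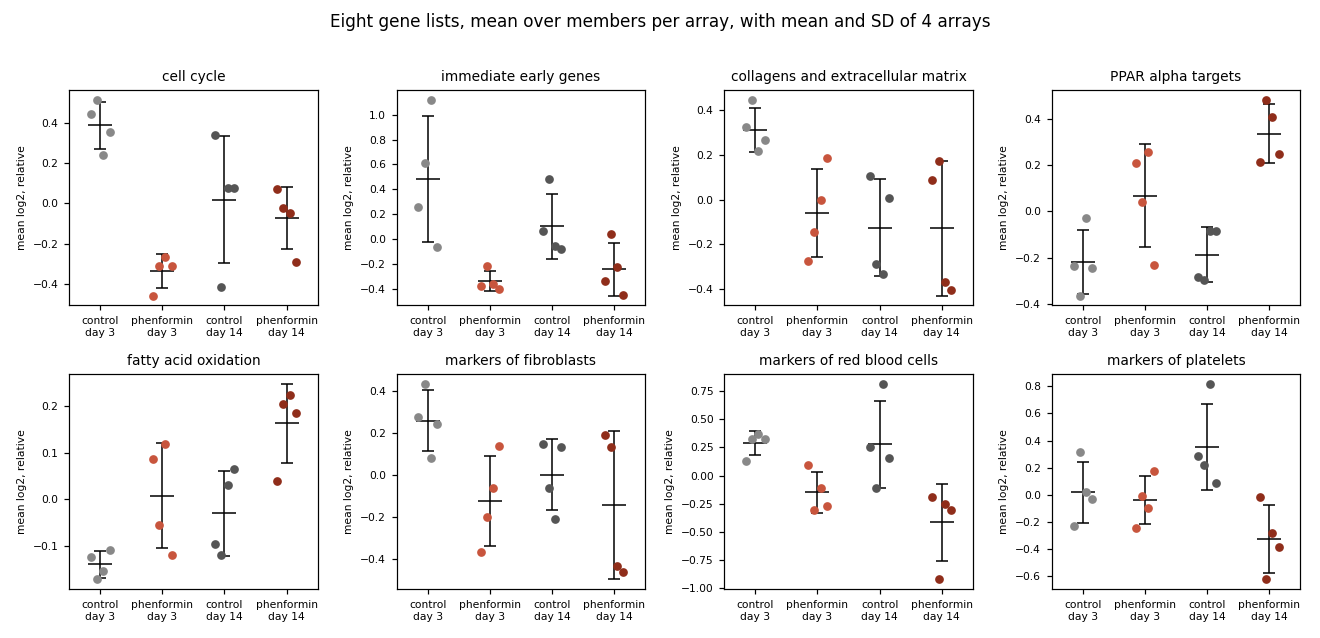
Mean log2 of 8 gene lists in each of the 16 arrays, each gene taken relative to its mean over all arrays, by group on the horizontal axis; points are arrays, and black bars give the mean and SD of 4 arrays. The cell cycle list had a mean of 0.389 in day 3 controls and -0.336 in day 3 treated arrays without overlap, and PPAR alpha targets a mean of -0.187 in day 14 controls and 0.336 in day 14 treated arrays.

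The day 14 comparison asks what the heart looked like after 14 days on the drug. Nr1d2 and Nr1d1 were again higher, by log2 changes of 2.00 (SE 0.229, adjusted p = 0.00339) and 2.44 (SE 0.342, adjusted p = 0.0161), which for Nr1d1 is 5.43-fold. The clock repressor gene Cry1 fell by 0.84 on the log2 scale (SE 0.127, adjusted p = 0.0307). Stc2, which encodes the secreted glycoprotein stanniocalcin 2, rose 1.59-fold (log2 change 0.67, SE 0.104), and the phosphatase gene Ptp4a3 rose 1.51-fold (0.60, SE 0.106). Ypel2 fell by 0.92 on the log2 scale (SE 0.114, adjusted p = 0.00496), and 2 genes of the iron-storage protein ferritin light chain, Ftl1 and its copy Ftl1l1, fell by 0.59 and 0.79 on the log2 scale (SE 0.0941 and 0.129, adjusted p = 0.0307 and 0.0387). The array cannot be assumed to separate near-identical copies such as these. The proline-pathway enzyme gene Aldh4a1 (-0.52, SE 0.091) and the membrane-shaping gene Pacsin2 (-0.49, SE 0.082) fell, and the zinc finger gene Zfp455l1 rose (0.55, SE 0.0966). A second, dimmer probe set of Aldh4a1 had a log2 change of -0.0414 and does not show the fall; the mean of both had -0.28 (adjusted p = 0.124). A second, dimmer probe set of Cry1 had -0.332.

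Several named genes of fat and glucose metabolism stood higher at day 14 without passing the test over all genes. Gpam, which starts triglyceride synthesis, had a log2 change of 0.93 (SE 0.168, adjusted p = 0.0522), and Txnip of 1.82 (SE 0.334, adjusted p = 0.0522). The carnitine palmitoyltransferase gene Cpt1a stood at 0.85 (SE 0.169) and the uncoupling protein gene Ucp3 at 1.53 (SE 0.314), each with adjusted p = 0.0679. Pdk4, which restrains glucose oxidation, had a log2 change of 2.34 with SE 0.771 (adjusted p = 0.269), and Angptl4 of 1.33 (SE 0.358, adjusted p = 0.167). PPAR alpha targets, the list that holds most of these, had a mean of 0.523 over 27 genes, with 0 past the threshold in limma and 15 higher adjusted over the list alone. The list test gave adjusted p = 2.2e-18 with the preset, adjusted p = 0.131 with an estimated correlation and 0.0226 by fry. Fatty acid oxidation had a mean of 0.194 over 29 genes, 26 of them above 0, with 6 higher and 1 lower adjusted over the list alone (Mlycd 0.44, SE 0.1; adjusted p = 0.362 with an estimated correlation). Triglyceride storage and lipolysis had a mean of 0.105 over 22 genes (Plin2 0.35; 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.581 with an estimated correlation). Fatty acid synthesis had a mean of -0.171 over 15 genes (Scd -0.37, Elovl5 -0.39; 2 lower adjusted over the list alone; adjusted p = 0.581 with an estimated correlation). That list kept its call in 15 alternatives and lost it in 13, 8 of them with 1 array left out. The triglyceride list lost its call in 8, 3 of them with 1 array left out.

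Blood cell markers were lower at day 14. Red blood cell markers had a mean of -0.694 over 10 genes (Slc4a1 -0.95, SE 0.226, adjusted p = 0.123; Ahsp -0.95, SE 0.281) and platelet markers of -0.68 over 8 (Tubb1 -1.04, SE 0.213, adjusted p = 0.0679; Treml1 -0.50). All 10 and all 8 were lower adjusted over the list alone, and 0 passed the limma test over all genes. Each list had adjusted p = 0.256 with an estimated correlation, while fry gave 0.0308 and 0.0226. Cytosolic heat shock genes were below 0 in 16 of 16 members with a mean of -0.248 (Hsph1 -0.60, SE 0.146; Hsp90ab1 -0.21, SE 0.0562; 4 lower adjusted over the list alone; adjusted p = 0.426 with an estimated correlation). Chaperones of the endoplasmic reticulum had a mean of -0.149 (Dnajb9 -0.31, Xbp1 -0.36; 0 lower adjusted over the list alone; adjusted p = 0.866 with an estimated correlation). The autophagy and lysosome list had a mean of -0.0938 over 27 genes (Gabarap -0.28, Map1lc3a -0.39; 1 lower adjusted over the list alone; adjusted p = 0.362 with an estimated correlation and 0.0226 by fry). Immediate early genes had a mean of -0.345 (Nr4a1 -1.72, SE 0.428, adjusted p = 0.137; Atf3 -1.51, SE 0.342, adjusted p = 0.111; 6 of 25 lower adjusted over the list alone; adjusted p = 0.866 with an estimated correlation). The autophagy and immediate early lists each lost their call in 7 alternatives, 3 and 4 of them with 1 array left out. The integrated stress response list had a mean of -0.136 over 41 genes while Stc2, a member, rose. In it 1 was higher and 5 lower adjusted over the list alone, and the adjusted p = 0.581 with an estimated correlation.

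Cardiac and stress markers at day 14 did not pass the test. Nppa had a log2 change of 1.94 (SE 0.42, adjusted p = 0.0904) with every treated array above every control, Nppb of -0.091 (SE 0.365) and Myh7 of 0.41 (SE 0.192, adjusted p = 0.452). The clock output gene Dbp stood at 0.87 (SE 0.206, adjusted p = 0.124) and the clock activator Bmal1 at -0.65 (SE 0.15, adjusted p = 0.113). Gdf15 (-0.13, SE 0.126), Fgf21 (-0.048, SE 0.151), Trib3 (-0.022, SE 0.168), Asns (-0.13, SE 0.0772) and Mthfd2 (-0.15, SE 0.123) had intervals that included 0. So did Nqo1 (0.087, SE 0.0776), Ppargc1a (-0.15, SE 0.15), Col1a1 (-0.28, SE 0.231) and Fkbp5 (-0.21, SE 0.121); Hmox1 had a log2 change of -0.39 (SE 0.184, adjusted p = 0.465).

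In all, 16 genes passed the threshold at day 14, 5 higher and 11 lower, and 9 also differed at least 1.5-fold; 2392 genes had an unadjusted p under 0.05 against 1105 expected. The count was 7, 7, 3, 6 and 5 without day 3 control replicates 1 and 2 and day 14 control replicates 1, 2 and 3, which share the estimate of the spread or the comparison. It was 9 and 29 without day 3 phenformin replicates 3 and 4, and 27, 9, 3 and 7 without day 14 phenformin replicates 1, 2, 3 and 4. Nr1d2 and Ypel2 passed without any single array, and Nr1d1 missed it without day 14 control replicate 1 and without day 14 phenformin replicate 3 (adjusted p of up to 0.0655). In all 9 of the 11 genes named as passing at day 14 missed it without between 2 and 15 of the 16 arrays, with adjusted p of up to 0.142. With array medians aligned the count was 3, 2 higher and 1 lower; with only the 8 arrays of that day it was 1, with the replicate number as a block 5, and without genes under the 50th percentile of mean level 60.

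Of the 55 lists, 11 passed the list test at day 14, 3 higher and 8 lower, and 6 without day 14 control replicate 1. None passed camera with an estimated correlation, where 6 lists had an unadjusted p under 0.05, and 4 passed fry: PPAR alpha targets, autophagy and lysosome, and markers of red blood cells and of platelets. Regrouping the same 8 arrays gave a median of 14 lists over the other 34 splits, above the 11 of the true grouping. In the exact permutation test of list means per array, 7 of 56 lists reached the smallest possible p of 0.0286 at day 14 and 6 did at day 3, where 1.6 were expected by chance, and 0 passed adjustment at either day.

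Effects at the 2 days were then set side by side. Their log2 changes rest on separate arrays, controls included. The spread of each gene, however, was estimated from the arrays of both days together. The same 5 genes passed the threshold at both days and in the same direction: Nr1d1 (log2 change 3.10 and 2.44), Nr1d2 (2.10 and 2.00), Cry1 (-0.94 and -0.84), Stc2 (0.48 and 0.67) and Ptp4a3 (0.55 and 0.60). Independent lists of these lengths would share 0.0905 genes. The shared estimate of spread can favour the same genes at both days. The lists are therefore not independent, and the 5 shared genes cannot be weighed against that number. With only the 8 arrays compared in the fit, 1 gene passed at day 14, so no more than 1 could then be shared. The 102 genes lower at day 3 had a median log2 change of -0.81 at day 3 and of -0.12 at day 14, and 85 of them were below 0 at day 14. The 23 genes higher at day 3 had medians of 0.56 and 0.24, with 18 above 0 at day 14. Across all genes the log2 changes of the 2 days correlated with r = 0.214 (jackknife SE 0.104) and rho = 0.137, and over the 136 genes past the threshold at either day with r = 0.711. Genes are not independent replicates, and the 136 were picked on these same changes, which can raise their r. Genes picked for large changes at day 3 can also have smaller medians at day 14 for that reason alone. The correlation was 0.402 without genes under the 50th percentile of mean level and 0.0445 with normal scores.

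**Figure D3:**
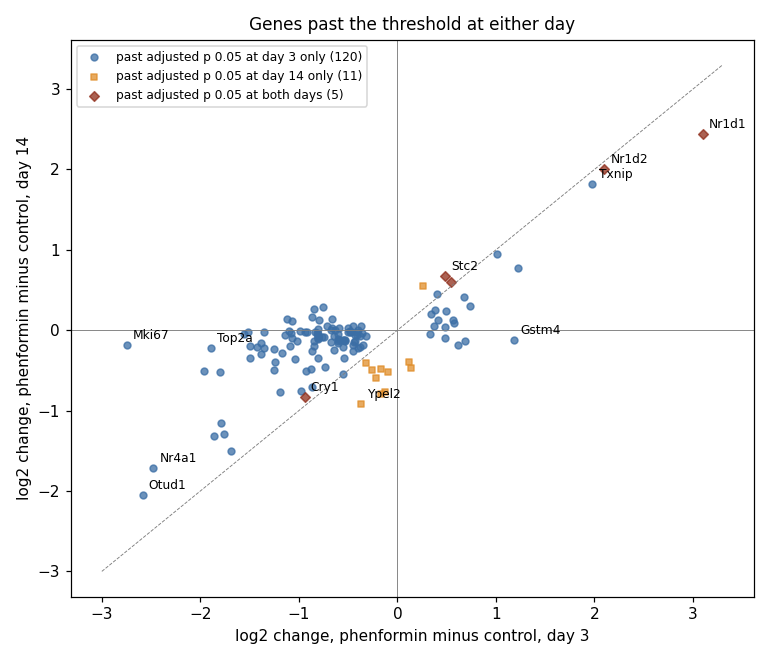
Log2 change, phenformin minus control, at day 3 on the horizontal axis and at day 14 on the vertical axis, for the 136 genes past adjusted p 0.05 at either day; colours give the day, and the dashed line marks equal changes. The 5 genes past the threshold at both days lie near that line, and most of the 102 genes that fell at day 3 lie near 0 at day 14, with a median of -0.12.

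The test of the difference between these effects, day 14 minus day 3, called 0 genes in limma, where 1546 had an unadjusted p under 0.05 and 1105 were expected; 1 gene was called without day 3 control replicate 2. Its smallest p belonged to Diaph3, an actin-nucleating protein chosen here after its values were seen, which had log2 changes of -0.99 at day 3 and -0.00392 at day 14 (difference 0.99, SE 0.18, adjusted p = 0.338). Differences between the days are therefore not established for any single gene. The list test of the difference is not counted as fixed in advance. The cell cycle list had a difference of 0.634 and 22 of 35 members higher adjusted over the list alone (adjusted p = 0.415 with an estimated correlation). The immediate early list had a difference of 0.474 (adjusted p = 0.932 with an estimated correlation), the collagen and matrix list of 0.368 (adjusted p = 0.932 with an estimated correlation) and platelet markers of -0.621 (3 of 8 lower adjusted over the list alone; adjusted p = 0.467 with an estimated correlation). In all 15 of 55 lists passed the list test of the difference, 6 higher and 9 lower, and the count was 7 without day 3 control replicate 3 and 8 without day 14 control replicate 1. In limma's camera 0 passed with an estimated correlation (3 at an unadjusted p under 0.05), and 1, autophagy and lysosome, passed fry.

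The control groups were compared between day 14 and day 3 to show what changed without the drug. The list test of this comparison is not counted as fixed in advance. Genes of branched-chain amino acid breakdown rose with time: 18 of 20 were above 0, 9 were higher adjusted over the list alone, and the mean was 0.206 (adjusted p = 0.0252 with an estimated correlation, 0.00079 by fry). Genes of autophagy and the lysosome rose too, with a mean of 0.159 over 27 genes and 7 higher adjusted over the list alone (adjusted p = 0.0252 with an estimated correlation). Examples chosen after their values were seen were Ivd (log2 change 0.43, SE 0.0755), Pink1 (0.42, SE 0.0675) and Gabarapl1 (0.71, SE 0.114), each with adjusted p = 0.0659 over all genes. The collagen and matrix list had a mean of -0.438 with 12 of 38 lower adjusted over the list alone (adjusted p = 0.258 with an estimated correlation). The cell cycle list had a mean of -0.37 with 18 of 35 lower adjusted over the list alone (adjusted p = 0.258 with an estimated correlation). Subunits of complex I had a mean of 0.145 with 33 of 34 above 0 (2 higher adjusted over the list alone; adjusted p = 0.359 with an estimated correlation).

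No single gene passed between the control groups: limma called 0, where 2091 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0659 (Clic5, log2 change 0.38, SE 0.0592). The count was 2 without day 3 control replicate 2, 24 without day 14 control replicate 1 and 4 without day 14 phenformin replicate 2, and 35 without genes under the 50th percentile of mean level. Of the 55 lists, 21 passed the list test, 15 higher and 6 lower, 2 with an estimated correlation and 5 by fry. The day of necropsy, the age of the rats and any batch between the days are one and the same here.

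This change with time and the effect of phenformin at day 3 are both measured against the day 3 controls. Across genes they correlated with r = 0.555, where unchanged groups simulated against shared controls gave a mean of 0.493; the covariance was 0.0202 against 0.0138. With the 4 day 3 controls split 2 and 2, so that no array served both comparisons, r averaged 0.145 over 6 splits (0.0788 to 0.231), and 12.3% of 1000 simulations gave as much. Lower cell cycle and matrix genes in both comparisons thus rest in part on the same 4 arrays. The day 14 controls are likewise shared by the change with time and the day 14 effect. The autophagy and lysosome list had a mean of 0.0909 in these controls and of -0.0681 in day 3 controls. It had -0.0198 in day 3 treated and -0.00289 in day 14 treated arrays. Its rise with time, its fall at day 14 and its difference between days thus rest in part on the same day 14 controls.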

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

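All tests of explanations in this part were chosen only after the results were seen. In 17 of 308 groups of 4 arrays, over the genes named in the report, 1 array lay far from the other 3, where 15.4 were expected by chance, and in 6 of 84 groups over the lists past the list test at day 3 or day 14, where 4.2 were. Day 3 control replicate 3 held 4 of these, the most of any array. It stood out in Nr1d2 (10.24 log2, against 9.514 in the mean of the others), Hadhb (16.42), Angptl4 (6.398) and the heat shock list (0.3123). Day 3 control replicate 1 stood out in Stc2 (8.403), Xbp1 (13.01) and Hsp90ab1 (15.48), and replicate 2 in Gpam (12.11), the endoplasmic reticulum chaperones (0.08587) and the autophagy and lysosome list (-0.03845).

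Day 14 control replicate 3 stood out in Arrdc4 (9.183), Chordc1 (12.75) and Myom2 (17.95), replicate 4 in Ppp1r15a (6.271) and replicate 2 in Irf9 (6.438). Day 14 phenformin replicate 4 stood out in Chordc1 (12.36) and Idh3a (15.91), and replicate 2 in the red blood cell list (-0.9228). Day 3 phenformin replicate 4 stood out in Slc4a1 (8.117) and the glucocorticoid list (-0.5043), replicate 2 in Hmox1 (6.917), and replicate 1 in Bmal1 (9.768) and the adult sarcomere list (0.08645).

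The list test of the difference between the effects, day 14 minus day 3, picked 15 lists, and 0 with an estimated correlation. Higher differences were found for the cell cycle (0.634), immediate early genes (0.474), collagens and matrix (0.368), acute phase genes (0.238), PPAR alpha targets (0.237) and fibroblast markers (0.235). Lower ones were found for platelet markers (-0.621), interferon-stimulated genes (-0.296), endothelial markers (-0.182), endoplasmic reticulum chaperones (-0.167), cytosolic ribosomal proteins (-0.15), autophagy and lysosome (-0.142), branched-chain amino acid catabolism (-0.118), complex II to V (-0.0934) and complex I (-0.093). Among the 44891 unnamed probe sets, left out of the gene test, 2 were called lower at day 3 when all probe sets were tested. Of them 2475 had an unadjusted p under 0.05 at day 3, where 2245 were expected. At day 14, 0 were called but 3825 had an unadjusted p under 0.05, the largest excess of the comparisons. The difference between days had 2616 and the controls over time 2864.

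Cell cycle genes were lower in treated hearts at day 3. Fewer cells of every type but muscle would move their markers alike if the expression per cell stayed the same. Fibroblast minus endothelial markers changed by -0.434 (exact p = 0.0286, the smallest possible), which argues against it under that premise only. Both list changes were known when this test was chosen, and fibroblast markers alone had exact p = 0.0571 at day 3. Fewer fibroblasts as the whole cause would lower both lists alike if the cycling share stayed the same, and cell cycle minus fibroblast markers changed by -0.344 (exact p = 0.0286). The pattern did not rest on day 3 phenformin replicate 1, without which the mean was -0.685. The list mean was 0.389 ± 0.117 (SD) in day 3 controls, 0.0188 ± 0.316 in day 14 controls and -0.336 ± 0.0833 in day 3 treated arrays. Day 3 treated arrays against day 14 controls had exact permutation p = 0.114. These groups also differ in age and day of necropsy, so this does not decide whether the day 3 controls were high by themselves. High day 3 controls, slower division with the drug and a loss of some dividing cell type stay open.

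Clock genes were shifted at both days; with the immediate early list mean of each array as a covariate, for a change at dissection, Nr1d2 kept log2 changes of 2.50 (SE 0.32, adjusted p = 0.0163) and 2.17 (SE 0.238), which argues against that change as the whole cause for Nr1d2. The changes of Nr1d1 went from 3.10 to 3.07 and from 2.44 to 2.43 and its SE from 0.342 to 0.522 and 0.388; its calls ended (adjusted p = 0.111 and 0.0542) with the larger SE and with fewer genes passing, which were not separated, and this leaves it open for Nr1d1 without speaking for it. It stays open too for Cry1 (-0.94, SE 0.127, to -0.79, SE 0.186), Per1 (-1.86, SE 0.359, to -0.86, SE 0.42) and Per2 (-0.98, SE 0.166, to -0.69, SE 0.233), whose day 3 calls ended with smaller changes and larger SE (adjusted p = 0.266, 0.974 and 0.652). The limma call of Cry1 at day 14 ended too (adjusted p = 0.0786), but its change went only from -0.84 (SE 0.127) to -0.77 (SE 0.138), which does not speak for this explanation. Only 2 genes at day 3 and 4 at day 14 were called with this covariate. Txnip was among them at both days, and its log2 changes were larger than without the covariate (1.98 and 1.82). They were 2.93 (SE 0.386, adjusted p = 0.0163 in limma) at day 3 and 2.22 (SE 0.288, adjusted p = 0.00898) at day 14. A different time of day or of feeding in treated rats would raise Nr1d1, Nr1d2 and Dbp and lower Bmal1, Npas2, Cry1 and Nfil3, but the difference of these sets, at least 2.17, rests on the Nr1d1 and Nr1d2 shifts that raised the question and decides nothing, and Npas2 went the other way (0.32 and 0.41). A direct effect of the drug on the clock would give the same, so these cannot be told apart here.

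Red blood cell and platelet markers were lower in treated hearts at day 14. Less blood left in the pieces would lower both by about the same, and the difference between their changes was -0.0146 (exact p = 0.943), whereas at day 3 the red blood cell list changed by -0.433 and the platelet list by -0.0583. It would also tie the lists together within groups: r was 0.626 (p = 0.05) and rho 0.529 (p = 0.068) over 16 arrays, but r was 0.294 without the 2 farthest arrays, so this stays open. Between the control groups the platelet list mean went from 0.0168 at day 3 to 0.352 at day 14 (exact permutation p = 0.143). The red blood cell list stood at 0.286 and 0.278. High platelet values in the day 14 controls thus enter the platelet fall at that day. Day 14 control replicate 3 was not the whole cause, since without it the lists changed by -0.516 and -0.525. An effect of the drug on blood cells was not tested.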

How the results depend on the processing

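Of the alternatives below, normal scores, dropping genes of mean log2 above 16 and leaving out the 2 arrays that stood apart were chosen only after the results were seen. All 125 genes called at day 3 kept their direction in every alternative that measured them, and the count of arrays limits what else can be told. Apart from the values below, counts stayed within 1.5 times. Unless stated, the cause was not tested. Day 3 genes: 74 with array medians aligned, 16 over all probe sets (more tests), 83 with 1.5-fold also required, 13 at adjusted p under 0.01, 23 without both arrays that stood apart (fewer arrays), and 22 to 149 with each array left out. Day 14 genes: 33 and 60 without genes under the 25th and 50th percentile (fewer tests), 3 with medians aligned, 3 without the trend, 8 with array weights, 1 with only the 8 arrays, 5 with the replicate block, 8 with the mean of probe sets, 2 over all probe sets, 9 with 1.5-fold, 2 at adjusted p under 0.01, 6 without both arrays, and 3 to 29 with each left out. Control genes over time: 14 and 35 under the same percentile filters and 0 to 24 with each array left out; the difference between days gave 0 to 1. Lists at day 3, day 14, in the difference and over time: 0, 0, 0 and 2 with an estimated correlation, and 1, 4, 1 and 5 by fry. The difference gave 8 lists without both arrays and 7 to 18 with each left out, and day 14 gave 6 to 15. The correlation of the days was 0.402 above the 50th percentile, 0.0445 with normal scores and 0.102 without both arrays. The replicate block gave 113 genes at day 3 and 5 at day 14; pairing by number was not borne out, as arrays of the same number had r of -0.185 to 0.0804 at day 3 and -0.127 to 0.113 at day 14. Of the lists past the list test, the FoxO and atrophy targets over time in controls changed direction (mean -0.02899 without day 3 control replicate 4; up to 0.1978 with another array left out). The genes that did were not called: Trib3 at day 14 (0.006477 with medians aligned; -0.1505 to 0.06598 with each array left out, with 0.007924, 0.0356 and 0.05703 between) and at day 3 (0.152 without both arrays; -0.1466 to 0.09395); Fgf21 at day 3 (0.07581 without both; -0.1811 to 0.0551) and day 14 (-0.1095 to 0.08801); Nppb at day 14 (0.0263 with array weights; -0.4347 to 0.2032, with 0.1664 and 0.1031) and day 3 (-0.002217 to 0.2817); and Pdk4 at day 3 (-0.1426 to 1.085, with -0.0496, -0.0476 and -0.04151).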

Other observations

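The families in this part were chosen after their values were seen; the regroupings of arrays were set before. Ferritin light chain symbols (Ftl1 and copies, iron storage) were below 0 at day 14 in 6 of 6 members, 2 of them called lower, with a median of -0.571 (-0.791 to -0.278). Their median was -0.192 at day 3 and 0.251 between the control groups. The ferritin heavy chain symbols had a median of -0.0944 at day 14, 6 of 6 below 0. Copies this alike can share probes, so the members are not independent.

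Mu-class glutathione S-transferases, which detoxify electrophiles, were above 0 at day 3 in 9 of 9 members, and in 8 with array medians aligned. Of these 3 rose past the threshold, Gstm4 (log2 change 1.19), Gstm6 (0.48, SE 0.084, adjusted p = 0.014) and Gstm6l (0.61, SE 0.116, adjusted p = 0.0228). At day 14, 8 of 9 were below 0 (median -0.123). Between the control groups 9 of 9 were above 0 (median 0.497), so low values in the shared day 3 controls enter both. Histone genes were below 0 in 36 of 46 members at day 3, with 6 called lower, and in 41 of 46 at day 14, with 0 called in limma (median -0.233 and -0.279).

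The arrays of each comparison were regrouped, in every way or in 100 drawn ways. At day 3, 1 of 35 splits, the real one, gave as many as 125 genes, and the highest other gave 1. At day 14, 1 of 35 gave as many as 16, and the highest other gave 5. The real grouping gave the largest count at each day, but 35 splits allow no share under 1 of 35. This argues against chance for these counts without excluding it, and under the settings of the report only. Other settings were not regrouped, and under some the day 14 count was 1, 3 or 5. Where 0 genes were called, for the difference between days and the controls over time, regrouping decides nothing, since all 100 of 100 and 35 of 35 splits reach 0 (highest other 2 and 1). Chance cannot be excluded for the counts of lists: at day 3, 2 of 35 splits gave as many as 17 (highest other 17), at day 14, 31 of 35 as many as 11 (highest other 23), for the difference, 25 of 100 as many as 15 (highest other 19), and for the controls over time, 3 of 35 as many as 21 (highest other 21). A correlation of the days as large as 0.214 came from 1 of 100 draws, the real one (highest other 0.16). This argues against chance without excluding it, and for the log2 values of all 16 arrays only. With normal scores the correlation was 0.0445 and without the 2 arrays that stood apart 0.102, and these were not regrouped.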
